A study of Arabidopsis thaliana with 36 samples.

How the data were processed

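Transcript levels of Arabidopsis thaliana were measured on 36 ATH1 arrays, 1 per RNA sample, in 12 groups of 3. Per the labels, each RNA sample was total RNA from a pool of 200 to 400 plants, and the labelled material was biotin-tagged cRNA made with an oligo-dT primer. The deposited values were scaled probe-set intensities on a linear scale, 1 per probe set and array, for 22810 probe sets. From the values themselves, the authors had scaled each array so that its 2% trimmed mean was 100.01, and the values ran from 0 to 7005.3. The software that summarised the probes is not given in the sources used here. Scanner background and raw array quality values were taken from the labels.

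The 64 control probe sets were left out of the comparisons. Of the other 22746, those with a mean intensity over all 36 arrays at or above the 30th percentile (14.7) were kept, which left 15924. The probe table used here gave 1 gene for 13513 probe sets, of which 13436 were found in the reference gene table, several genes for 503 and none for 8730. Of the 15924 tested, 8857 had 1 gene, and the others entered the counts without a name. Most genes were named by locus number alone (11933 of 13513), since a symbol was given for 1580. No genome build was needed, and positions are not given.

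Intensities were transformed as log2 of the value plus 16, a pseudocount that damps noise near the floor, so a log2 difference of a dim gene is smaller than the log2 of its fold change. No further normalization between arrays was added. A linear model with 12 group means was fitted to each probe set with limma 3.58.1 in R 4.3.3, with 24 residual degrees of freedom, a variance prior that followed mean intensity, and a prior of 6.26 degrees of freedom. Each comparison was a two-sided limma contrast, and p-values were adjusted by the Benjamini-Hochberg method over the 15924 probe sets within a comparison, with a threshold of 0.05. Every adjusted p of a gene in the text comes from this fit, and "called" means past that threshold. Tissue was compared as the mean of the xylem minus cork difference over 3 genotypes. Mutants were compared with the wild type of the same family, and differences of effects were tested as contrasts of their own, because mutants of one family shared their control arrays.

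The genes named were chosen by a rule written before the data were examined. It took up to 10 largest rises and 10 largest falls per comparison (5 and 5 for differences of effects) among called probe sets with 1 gene whose compared groups did not overlap. For xylem versus cork this was asked within each genotype, and for the MYB61 and MYB50 differences of effects and MYB61 versus MYB50, which span 4 groups, it was not asked. It also took up to 4 called members of each gene list with the smallest adjusted p, or, where no member was called, up to 2 with the largest difference. The rule also asked for the targeted gene of each mutant, which no probe set named.

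Of 418 genes in 30 lists fixed before the data were examined, 45 had a probe set named in the table, and 6 lists had at least 3 tested members. Tested were 3 of 14 xylan, 3 of 19 phloem and 4 of 19 cambium genes. Of the ABA-responsive, auxin-responsive and glucosinolate genes, 3 of 32, 3 of 29 and 3 of 21 were tested. A list result covers those members alone. A further 29 lists of gene families and functions were not planned: they were written after the probe table was seen, from its symbols, though before any comparison was computed. Lists were tested with limma's camera at a preset correlation of 0.01, with camera at an estimated correlation, and with fry, adjusted over the lists within a comparison. The model was tested on simulated data with known changes: for abi1 against Ler it recovered 70.1% of changes of 0.5 on the log2 scale and 98.5% of changes of 1, with 3.8% of its calls false. For a difference of effects it recovered 25.4% and 92.5%, with 6.5% of its calls false. The simulated noise was independent and normal with the variances of the fit, so the assumptions of the model held by construction. Deviations shared between probe sets and arrays of unequal quality were not simulated.

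The alternatives were pseudocounts of 1 and 64, no filter and a filter at the 50th percentile, quantile normalization, the replicate block (the replicate number as a fixed term within each family), array quality weights, the scanner background as a covariate, robust variance moderation, fits of only the arrays of the groups compared, and fits without each array in turn. Besides the added lists, the tissue comparison in Col-0 alone was added after the data were seen, as were the fits without both a MYB61 knockout cork array with low weight and a MYB50 knockout cork array that the labels mark as a repeat. The actin 3' to 5' ratio was used as a covariate in a test of RNA quality. Other splits of the samples were drawn up to 100 times. Tables were prepared with Python 3.11.15, numpy 2.4.6, scipy 1.17.1 and pandas 2.3.3, and plots with matplotlib 3.10.9. Array values carry no counts, so the number of arrays limits the precision.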

Results

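Transcript levels were measured in Arabidopsis, in a series on how dormancy and secondary growth, the thickening made by the vascular cambium, relate to each other. Xylem and cork were sampled from wild-type Col-0 and from knockouts of MYB61 and of MYB50, a pair of related transcription factor genes. Hypocotyls were sampled from abi1 (insensitive to abscisic acid, ABA) and aba1 (ABA-deficient) with wild-type Ler, and from max4 (strigolactone-deficient) and axr1 (auxin-resistant) with wild-type Col-0. Each of the 12 groups had 3 arrays, and each array took RNA of 200 to 400 pooled plants. What the cork samples held besides cork is not given in the labels. Intensities below are scaled probe-set intensities, as mean ± SD, and log2 differences carry their standard error (SE).

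Array medians lay between 35.1 and 44.9, and 29.6% to 37.1% of the probe sets of an array were under 16. The scanner background ran from 64.2 to 132 and the 3' to 5' ratio of actin from 1.07 to 2.11. Arrays of a group correlated with each other at 0.958 to 0.993, arrays of different groups at 0.807 to 0.986, and each of the 36 arrays correlated best with its own group. The 25S ribosomal RNA control ranged from 45.6 to 3027 between arrays. Its mean was 66.4 ± 18.6 in Ler and 2820 ± 189 in Col-0 cork (SD, n = 3). No probe set named MYB61, MYB50, ABI1, ABA1, MAX4 or AXR1, so the mutants were not checked here by the level of the targeted gene.

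**Figure D1:**
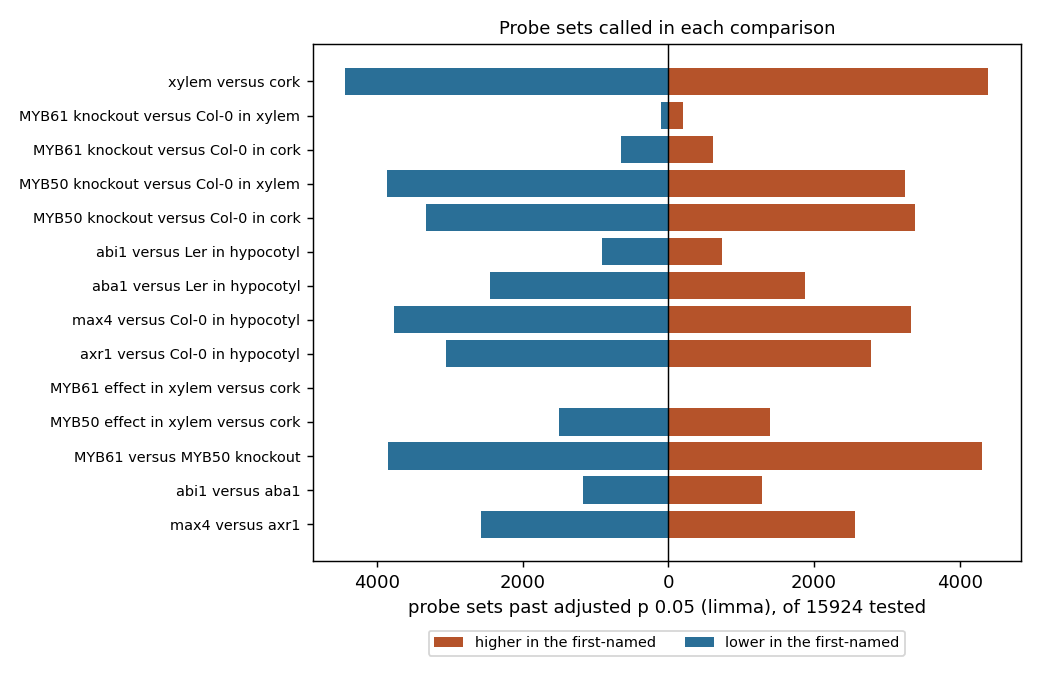
Number of probe sets past the limma threshold in each of the 14 comparisons, of 15924 tested; bars to the right count probe sets higher in the first-named group or effect, bars to the left those lower. Xylem versus cork has the longest bars (4394 and 4437), and the difference of the MYB61 effects the shortest (13 and 5).

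Xylem and cork were compared over the 3 genotypes to describe the tissues sampled. CLE41, which encodes a phloem-made peptide that signals to the cambium, was at 29.4 ± 5.70 in xylem and 572 ± 297 in cork (SD, n = 9, genotypes pooled), 19.5-fold higher in cork. OCT1, a transporter of the carnitine transporter family, was at 1134 ± 623 in xylem and under 16, near the background, in cork (mean 13.2), the subtilase gene ATSBT5.2 was 46.6-fold higher in xylem, and AT4G30460, a gene for a glycine-rich protein, 67.0-fold higher. The beta-glucosidase genes PYK10 and BGLU33 were 19.8-fold and 25.1-fold higher in cork, and AT2G25450, an oxygenase of glucosinolate side chains, was at 332 ± 48.6 in cork and near the background in xylem (13.8 ± 7.77). Each of these genes had adjusted p of 4e-22 or below and did not overlap between xylem and cork in any of the 3 genotypes.

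Of the phloem markers, 3 of 3 tested fell in xylem (CLE41 by log2 -3.56, SE 0.06; SWEET11 -1.0, SE 0.07; OPS -0.40, SE 0.08), as did 3 of 3 adjusted over the list alone, and camera called the list (adjusted p = 0.00254, and adjusted p = 0.0334 with an estimated correlation). The xylan synthesis genes GUT2 (IRX10), IRX15 and IRX15-L were 3 of 3 higher in xylem, 3 adjusted over the list alone (log2 1.45, 1.65 and 0.82); camera called the list at adjusted p = 0.0081, with adjusted p = 0.149 with an estimated correlation. Glucosinolate genes fell in xylem in 3 of 3, and 3 adjusted over the list alone, among them BCAT4 (log2 -2.25, SE 0.18), the first enzyme of side-chain elongation; camera gave adjusted p = 0.00254, and adjusted p = 0.066 with an estimated correlation. In the cambium list PHV, a class III HD-ZIP factor, was 588 ± 95.1 in xylem and 124 ± 19.0 in cork (log2 2.11), the receptor kinase gene MOL1 fell in xylem (log2 -0.93), and the list as a whole was not called (adjusted p = 0.891). The suberin-associated acyltransferase gene FACT fell in xylem (log2 -2.15), and the lignin gene HCT rose (log2 0.87).

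Among the added lists, 6 of 7 tau glutathione transferases fell in xylem (GSTU20 by log2 -2.61, GSTU16 by -2.06), with camera adjusted p = 0.000149 and adjusted p = 0.0296 with an estimated correlation. Of 25 UDP-glycosyltransferases, 15 fell (UGT78D1 log2 -2.30) and 3 rose (camera adjusted p = 0.00476, and adjusted p = 0.0296 with an estimated correlation). Nuclear photosynthesis genes fell in 19 of 21 (PSAE-1 log2 -1.93, PSB27 -1.92; camera adjusted p = 1.33e-08, and adjusted p = 0.116 with an estimated correlation). Over all probe sets limma called 8831 of 15924, 4394 higher and 4437 lower in xylem, of which 502 and 889 changed at least 2-fold. The balance turned to 5208 higher and 4166 lower with quantile normalization and to 3707 and 3236 with the stricter filter. Within genotypes the counts were 6399 in Col-0, 5388 in the MYB61 knockout and 6407 in the MYB50 knockout, and 3027 probe sets were called the same way in each of the 3. In Col-0 arrays alone, a comparison added after the data were seen, the difference was log2 0.78 for IRX15 (adjusted p = 0.045) and 0.95 for GUT2, and IRX15-L (0.41) and OPS (-0.22) were not called (adjusted p = 0.096 and 0.19).

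The MYB61 knockout was compared with Col-0 in xylem to describe transcripts that differ between them. AT4G29780 stood at 830 ± 388 against 156 ± 19.6 in Col-0 (SD, n = 3; log2 2.22, SE 0.31, adjusted p = 5.1e-05), and ORA47, an AP2/ERF factor, at 561 ± 161 against 109 ± 18.5 (log2 2.18, SE 0.27, adjusted p = 1.3e-05). The calmodulin-like gene CML38 rose 3.70-fold. AT2G15560 was 7.36-fold lower in the knockout (28.2 ± 3.13 against 208 ± 63.9), and the cytosolic Hsp70 gene AT3G09440 was 2.77-fold lower. Of the xylan genes, 0 of 3 were called by limma, 0 adjusted over the list alone (IRX15 log2 -0.23, adjusted p = 0.87; GUT2 -0.21, adjusted p = 0.67), with camera adjusted p = 0.6.

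The 3 ABA-responsive genes tested, of 32 listed, rose as a list. Of them 1 was called, the dehydrin COR47 (260 ± 49.1 against 101 ± 25.6, adjusted p = 0.00036), and 2 were called when adjusted over the list alone. Camera called the list at adjusted p = 0.000624, and at adjusted p = 0.0389 with an estimated correlation. Nuclear photosynthesis genes gave 2 of 21 lower (LHCB4.2 log2 -0.87, ATPC1 -0.57), with camera adjusted p = 6.35e-09 and adjusted p = 0.31 with an estimated correlation. Of the 373 probe sets at least 2-fold higher in both max4 and axr1, described below, 115 were called higher here. In all, limma called 299 probe sets, 194 higher and 105 lower. The count was 39 when only the arrays of both groups were fitted, where CML38 was not called (adjusted p = 0.051), 193 without Col-0 xylem replicate 3, and 174 without MYB61 knockout xylem replicate 2, where 89 were higher and 85 lower. LHCB4.2 lost its call under 4 alternatives and ATPC1 under 7.

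In cork the MYB61 knockout showed higher AT4G29780 (767 ± 442 against 110 ± 38.0, SD, n = 3; log2 2.55, SE 0.31, adjusted p = 3.2e-06), AT2G27080 (5.46-fold), AT1G74450 (4.32-fold) and ORA47 (5.83-fold). The zinc-finger gene STZ (ZAT10) rose from 589 ± 92.9 to 1672 ± 438. AT3G09440 was again lower (2.89-fold), as was MSRB5, a methionine sulfoxide reductase gene (3.58-fold). Some transcripts of the organelle genomes fell, rpl14 by log2 -1.43, rpl16 by -1.19 and psbA by -1.49 from the plastid, cox1 by -0.95 and nad5 by -0.90 from the mitochondrion.

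By list, 15 of 43 plastid-encoded photosynthesis genes fell and 1 rose (camera adjusted p = 3.8e-11, and adjusted p = 0.254 with an estimated correlation), 7 of 20 plastid genes for gene expression fell (camera adjusted p = 1.66e-07, and adjusted p = 0.184 with an estimated correlation), and 5 of 13 mitochondrial genes fell (camera adjusted p = 1.24e-07, and adjusted p = 0.118 with an estimated correlation). The 25S ribosomal RNA control, also without a poly(A) tail, was 1493 ± 1157 in these knockout arrays and 2820 ± 189 in Col-0 cork. The xylan, glucosinolate and phloem lists were not called (camera adjusted p = 0.666, 0.491 and 0.558). limma called 1274 probe sets, 619 higher and 655 lower. The scanner background differed between the groups (108 ± 16.4 against 73.4 ± 3.48), and with it as a covariate the count was 500 (260 higher, 240 lower); it was 230 with only the arrays of both groups, 780 without Col-0 cork replicate 1 and 774 without Col-0 cork replicate 2. With the actin 3' to 5' ratio as a covariate it was 654.

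Xylem of the MYB50 knockout was compared with Col-0 xylem in the same way. IRX15 was at 360 ± 86.2 against 39.4 ± 47.8 (SD, n = 3; log2 3.09, SE 0.31, adjusted p = 2e-09), IRX15-L at 420 ± 92.1 against 55.1 ± 21, and GUT2 at 525 ± 89.3 against 113 ± 46.3. TBL36, of the family of wall polysaccharide acetyltransferases, rose 9.29-fold, the pectate lyase-like genes AT1G04680 and AT1G67750 rose 10.9-fold and 11.9-fold, and the glucanase gene AT4G16260 rose 13.9-fold. NRT2.5, a high-affinity nitrate transporter, was 9.50-fold lower (34.6 ± 12.4 against 328 ± 81.9), AT3G21670 of the nitrate transporter family 5.78-fold lower, and the glutaredoxin-family gene AT4G33040 6.22-fold lower.

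Of the xylan genes 3 of 3 rose, 3 adjusted over the list alone; camera called the list at adjusted p = 0.000138, with adjusted p = 0.0672 with an estimated correlation. The added lists gave 5 of 8 GH9 endoglucanases higher (GH9B5 log2 2.11, GH9B7 2.09; camera adjusted p = 0.000518, and adjusted p = 0.0171 with an estimated correlation), 8 of 14 TBL acetyltransferases (TBL34 log2 1.41; 0.00135 and 0.00816) and 11 of 17 serine carboxypeptidase-like genes (SCPL45 log2 1.97; 6.32e-05 and 0.00816). The 6 RALF peptide genes tested all rose, RALFL24 by log2 1.63 (camera adjusted p = 0.000518, and adjusted p = 0.0352 with an estimated correlation). Expansins rose in 5 of 9 (EXLA3 log2 2.73, EXPA4 1.78) and fell in 1 (camera adjusted p = 0.0361, and adjusted p = 0.111 with an estimated correlation). The ABA-responsive list had 2 of 3 higher (COR47 log2 1.29, LTI30 1.84), 2 adjusted over the list alone, without a camera call (adjusted p = 0.363). The auxin-responsive list had 2 of 3 lower, 2 adjusted over the list alone, with camera adjusted p = 0.492. limma called 7109 probe sets, 3249 higher and 3860 lower; at least 2-fold changes were 871 and 280.

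In cork, the MYB50 knockout had CLE41 at 966 ± 55.5 against 354 ± 12.5 (SD, n = 3; log2 1.41, SE 0.11, adjusted p = 1.4e-11). The aspartyl protease-family gene AT1G09750 rose from 17.0 ± 0.500 to 815 ± 53.0, the subtilase gene SBT4.12 rose by log2 3.52, and EXPB3, a beta-expansin gene, rose from 157 ± 12.8 to 1080 ± 66.9. TBL36 rose 11.6-fold. NRT2.5 was 12.5-fold lower, AT3G21670 10.0-fold lower and AT1G80130 33.6-fold lower. PPDK and APL3, genes of pyruvate and starch metabolism, were 6.03-fold and 4.66-fold lower.

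Of the phloem markers CLE41 and OPS rose (log2 1.41 and 0.89) and SWEET11, a sucrose exporter, fell (log2 -0.68), 3 of 3 adjusted over the list alone, and camera did not call the list (adjusted p = 0.315). Of the xylan genes IRX15-L rose (log2 1.02), with 2 of 3 adjusted over the list alone and no camera call (adjusted p = 0.315). FACT rose (log2 0.90). The auxin-responsive list had 1 of 3 lower, 3 adjusted over the list alone, with camera adjusted p = 0.315. Expansins rose in 7 of 9 (camera adjusted p = 0.00163, and adjusted p = 0.0235 with an estimated correlation), RALF peptide genes in 6 of 6 (RALFL34 log2 2.38; 0.000203 and 0.0235) and GH9 endoglucanases in 4 of 8 (GH9B13 log2 2.44; 0.00163 and 0.0235). Plastid-encoded photosynthesis genes fell in 25 of 43 and rose in 2 (psbZ log2 -1.28; camera adjusted p = 0.000203, and adjusted p = 0.464 with an estimated correlation). The 25S control was 766 ± 629 in these arrays. limma called 6715 probe sets, 3388 higher and 3327 lower (3136 and 3771 with quantile normalization, 2416 and 2951 with the stricter filter). It called 6339 without the MYB61 knockout cork array of low weight and the MYB50 knockout cork array labelled a repeat, a fit added after the data were seen.

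**Figure D2:**
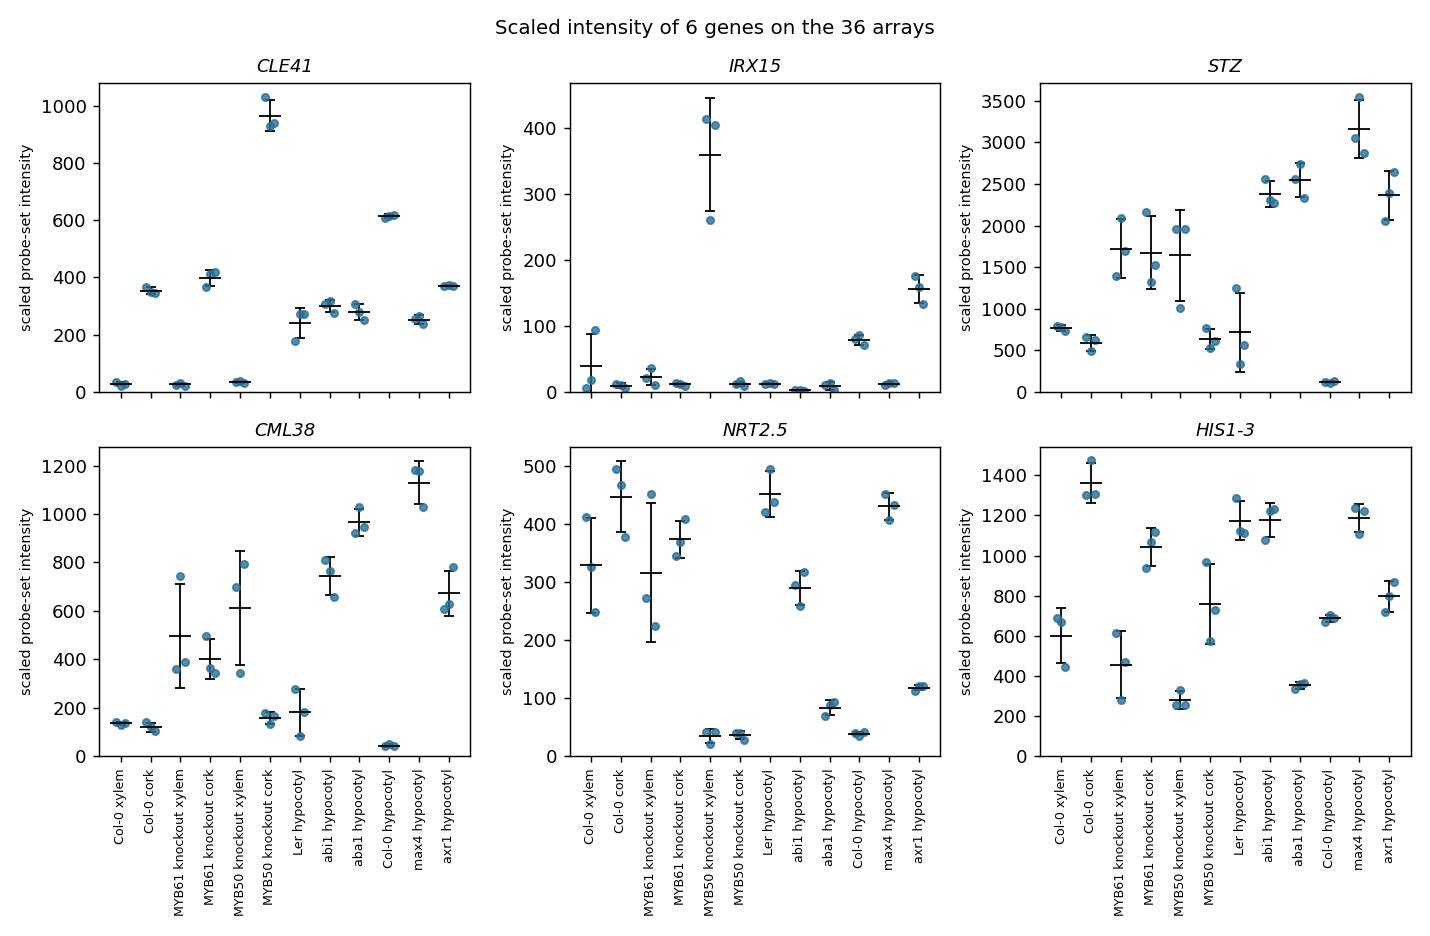
Scaled probe-set intensity (linear axes) of 6 genes on the 36 arrays, by group; points are single arrays, horizontal marks the group mean and bars 1 SD (n = 3). CLE41 is at 966 in MYB50 knockout cork and 34.5 in MYB50 knockout xylem; IRX15 is at 360 in MYB50 knockout xylem; STZ and CML38 are lowest in Col-0 hypocotyls (119 and 43.2); NRT2.5 is at 34.6 and 35.8 in the MYB50 knockout tissues; HIS1-3 is at 353 in aba1 and 1174 in Ler.

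Whether a knockout acted alike in xylem and cork was tested as a difference of its effects. For MYB50 the xylan genes differed: IRX15 rose more in xylem than in cork (difference of log2 effects 2.94, SE 0.44, adjusted p = 1.3e-05), as did GUT2 (1.74) and IRX15-L (1.61), 3 of 3 and 3 adjusted over the list alone, and camera called the list (adjusted p = 3.09e-05, and adjusted p = 0.0409 with an estimated correlation). AT1G09750 (-4.39, SE 0.16), SBT4.12 (-3.21) and CLE41 (-1.20) rose more in cork. IRX15 was under 16, near the background, in cork of both genotypes, as was SBT4.12 in xylem. AT1G09750 was near the background in xylem too. limma called 2896 probe sets, 1390 with the higher effect in xylem and 1506 with the higher effect in cork. For MYB61, MSRB5 differed (1.5, SE 0.18, adjusted p = 3.4e-05), and so did the mitochondrial gene cox1 (0.97, SE 0.18, adjusted p = 0.011) and COR47 (1.41, SE 0.29, adjusted p = 0.035), of which 12 of 22 alternatives ended the call of COR47 and 3 that of cox1. In xylem MSRB5 was under 16, near the background, in both genotypes, so a fall like that in cork could not be seen there. The ABA-responsive list had 1 of 3 called, 2 adjusted over the list alone, with camera adjusted p = 0.00289 and adjusted p = 0.078 with an estimated correlation.

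The MYB61 count was 18 probe sets, 13 higher and 5 lower. It moved with single arrays: 33 without Col-0 xylem replicate 1, 6 and 32 without Col-0 cork replicates 2 and 3, 9 without MYB61 knockout xylem replicate 1, and 150 and 11 without MYB61 knockout cork replicates 1 and 2. Changing the settings gave 10 with the stricter filter, 200 with array weights, 8 with the background covariate and 3 with only the arrays of these groups.

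The knockouts were also compared with each other over both tissues. Nitrate transporter genes NRT2.5 (log2 2.80, SE 0.13) and AT3G21670 (2.82, SE 0.10) were higher in the MYB61 knockout. TBL36 (-3.43, SE 0.14), AT1G04680 (-3.50, SE 0.12) and AT1G67750 (-2.95, SE 0.11) were lower there than in the MYB50 knockout. Xylan genes were 3 of 3 lower in the MYB61 knockout, 3 adjusted over the list alone, with camera adjusted p = 0.00307 and adjusted p = 0.201 with an estimated correlation. GH9 endoglucanases were lower in 7 of 8 and beta-glucosidases in 9 of 11 (camera adjusted p = 6.92e-05 for each, and adjusted p = 0.00627 with an estimated correlation for each). limma called 8153 probe sets, 4308 higher and 3845 lower in the MYB61 knockout. In xylem 159 probe sets were higher in both knockouts than in Col-0. The knockouts shared the Col-0 arrays: the covariance of their log2 differences was 0.049 (r = 0.38), and 0.0098 (r = 0.5) in data simulated with shared controls and no effects.

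The abi1 hypocotyls were compared with Ler to describe tissue that responds poorly to ABA. AT4G29780 was at 1300 ± 70.5 against 65.2 ± 34.0 in Ler (SD, n = 3; log2 4.1, SE 0.31, adjusted p = 9.3e-11), ORA47 was 12.4-fold higher, the calmodulin-like genes CML37 and CML38 rose by log2 2.76 and 2.08, and the glutaredoxin gene GRX480 by 2.84. In Ler CML37 was under 16, near the background (3.3 ± 2.29). BCAT4 rose from 79.0 ± 13.8 to 567 ± 179. OCT1 was 3.29-fold lower, and FACT fell from 269 ± 6.31 to 110 ± 10.6. The ABA- and cold-responsive dehydrin LTI30 fell by log2 -1.37 (SE 0.39, adjusted p = 0.021).

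Glucosinolate genes rose in 3 of 3 (BCAT4 log2 2.58, AT2G31790, also known as UGT74C1, 0.77, UGT74B1 0.53), 3 adjusted over the list alone, and camera called the list at adjusted p = 5.42e-05 and at adjusted p = 0.0208 with an estimated correlation. Of the ABA-responsive genes 1 of 3 fell, 1 adjusted over the list alone, with camera adjusted p = 0.452. The auxin-responsive list had 2 of 3 lower, 2 adjusted over the list alone, with camera adjusted p = 0.16. Calmodulin-like genes rose in 3 of 7 (camera adjusted p = 0.00106, and adjusted p = 0.374 with an estimated correlation). limma called 1661 probe sets, 743 higher and 918 lower. The count was 3219 with array weights, 1018 with only the arrays of both groups (542 higher, 476 lower), 1102 and 1066 without Ler replicates 2 and 3, and 940 without abi1 replicate 2. Without either of those Ler arrays or without abi1 replicate 3 LTI30 was not called, and with a pseudocount of 1 neither was AT2G31790 (adjusted p = 0.089).

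The aba1 hypocotyls, which make little ABA, were compared with Ler. HIS1-3, a drought-induced linker histone gene, was 3.33-fold lower (353 ± 18 against 1174 ± 97.3, SD, n = 3; log2 -1.69, SE 0.18, adjusted p = 1.3e-08), LTI30 5.48-fold lower, and AtLEA4-1 and XERICO fell by log2 -1.35 and -1.1. OCT1 was 21.9-fold lower and NRT2.5 5.44-fold lower. AT4G29780 was 31.6-fold higher, CML37 rose by log2 4.33 and GRX480 by 3.72. In Ler CML37 was under 16, near the background (3.3 ± 2.29). The small heat shock genes AT1G53540 and ATHSP22.0 were higher but uneven between arrays, at 644 ± 383 against 13.2 ± 3.25 and at 260 ± 227 against 16.4 ± 0.265.

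ABA-responsive genes fell in 2 of 3 (LTI30 log2 -2.13, COR47 -0.83), 2 adjusted over the list alone, without a camera call (adjusted p = 0.165). The auxin-responsive list had 2 of 3 lower, 2 adjusted over the list alone, with camera adjusted p = 0.25. PHV fell (log2 -0.87), SWEET11 fell (log2 -1.24) and FACT fell (log2 -0.71). PUB ubiquitin ligase genes rose in 3 of 7 (PUB23 log2 3.17, PUB22 2.62), with camera adjusted p = 0.0497 and adjusted p = 0.341 with an estimated correlation. limma called 4317 probe sets, 1873 higher and 2444 lower. With array weights the count was 6892.

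Set against each other, abi1 had more BCAT4 (log2 2.26, SE 0.31) and COR27 (2.45, SE 0.39), HIS1-3 (1.69) and AtLEA4-1 (1.45) than aba1. The heat shock genes AT1G53540 (-4.46, SE 0.23), AT2G29500 (-3.82, SE 0.26) and ATHSP22.0 (-2.89, SE 0.32) were lower in abi1. There they were under 16, near the background (means 10.5, 4.87 and 12.5). In aba1 they were uneven between arrays (644 ± 383, 325 ± 224 and 260 ± 227). Cold and dehydration genes were higher in abi1 in 5 of 14 (camera adjusted p = 0.000133, and adjusted p = 0.0476 with an estimated correlation). limma called 2456 probe sets, 1285 higher and 1171 lower. Against the Ler arrays that both mutants shared, 539 probe sets were higher in both and 564 lower in both. The covariance of the log2 differences was 0.1149 (r = 0.71), and 0.0097 (r = 0.5) in data simulated with shared controls and no effects.

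The max4 hypocotyls were compared with Col-0 to describe tissue short of strigolactone. STZ stood at 3159 ± 346 against 119 ± 8.89 (SD, n = 3; log2 4.56, SE 0.27, adjusted p = 1.6e-14), AT4G29780 was 45.8-fold higher and CML38 rose by log2 4.27. The germin-like gene AT3G05950 rose from 38.1 ± 3.71 to 1320 ± 89.9. AT5G19120 of the aspartyl protease family was 10.9-fold lower and JRG21, a jasmonate-responsive oxygenase gene, 8.28-fold lower. CLE41 fell from 614 ± 5.85 to 253 ± 14.7, and IRX15 from 78.5 ± 7.48 to 12.4 ± 1.70.

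Of the phloem markers CLE41 (log2 -1.23) and SWEET11 (-1.28) fell and OPS rose (0.66), 3 of 3 adjusted over the list alone, without a camera call (adjusted p = 0.465). In the cambium list PHV (log2 0.63) and MOL1 (0.34) rose, 2 of 4 and 2 adjusted over the list alone (camera adjusted p = 0.634). Of the auxin-responsive genes WES1 (GH3.5) fell (log2 -1.40), with 2 of 3 adjusted over the list alone; the list had a median of 0.171 and a mean of -0.222, of opposite sign, and camera adjusted p = 0.837. Calmodulin-like genes rose in 6 of 7 (camera adjusted p = 0.000693, and adjusted p = 0.289 with an estimated correlation). limma called 7105 probe sets, 3336 higher and 3769 lower.

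The axr1 hypocotyls, impaired in auxin response, showed AT5G05890, a UDP-glycosyltransferase-family gene, at 1742 ± 99.8 against 24.6 ± 1.82 in Col-0 (SD, n = 3; log2 5.44, SE 0.13, adjusted p = 2.3e-24). STZ was 19.9-fold and CML38 15.5-fold higher. The thionin gene THI2.1 was 22.7-fold lower (51.9 ± 5.70 against 1176 ± 56.6), and the carboxypeptidase-like genes scpl31 and scpl30 were 8.30-fold and 6.44-fold lower. CLE41 fell by log2 -0.70, and FACT rose by 1.1.

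Xylan genes rose in 3 of 3 (GUT2 log2 0.96, IRX15 0.86, IRX15-L 0.71), 3 adjusted over the list alone, with camera adjusted p = 0.0576; 5 of 15 alternatives ended the call of IRX15. The auxin-responsive list, with 3 of 29 genes tested, had 0 called by limma and 0 adjusted over the list alone. HAT2 changed by log2 0.48 and WES1 by -0.46 (adjusted p = 0.12 for each), and the list had camera adjusted p = 0.823. Mitochondrion-encoded genes fell in 11 of 13 (ccb452 log2 -1.14, nad9 -1.09; camera adjusted p = 0.000158, and adjusted p = 0.218 with an estimated correlation), while the 25S control was 2506 ± 441 against 2380 ± 362. limma called 5833 probe sets, 2779 higher and 3054 lower.

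Compared with each other, max4 had more AT3G05950 (log2 4.61, SE 0.24) and THI2.1 (3.64, SE 0.24) and less AT5G05890 (-5.13, SE 0.13) than axr1. Xylan genes were lower in max4 in 3 of 3 (IRX15 log2 -2.59, GUT2 -1.22, IRX15-L -1.09), 3 adjusted over the list alone, with camera adjusted p = 0.00112 and adjusted p = 0.139 with an estimated correlation. Mitochondrion-encoded genes were higher in max4 in 9 of 13 (camera adjusted p = 4.73e-06, and adjusted p = 0.111 with an estimated correlation). limma called 5135 probe sets, 2568 higher and 2567 lower. Against the shared Col-0 arrays 1736 probe sets were higher in both mutants and 2017 lower in both. The covariance of their log2 differences was 0.2327 (r = 0.70), and 0.0097 (r = 0.5) in data simulated with shared controls and no effects. Of the 373 probe sets at least 2-fold higher in both, STZ and CML38 among them, 59.2% were also called higher in abi1 and 30.8% in MYB61 knockout xylem, and on arrays of the 9 other groups the set varied 2.18 times as much between replicates as probe sets of like intensity.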

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

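The tests of the interactions with additive effects removed were chosen after the result was seen. The effect of the MYB61 knockout differed between xylem and cork at 18 probe sets by the interaction contrast of limma, and that of the MYB50 knockout at 2896, which is why both are listed here.

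For MYB61 chance could not be excluded: 21 of 100 splits, the real one included, gave as many as the real 18, and the highest other gave 718. For MYB50, 8 of 100 splits, the real one included, gave as many as the real 2896, and the highest other gave 8810, so chance was not excluded by this count either. Splits that exchange genotypes in 1 tissue alone turn the genotype effect itself into an interaction, and splits with several times the real count point to that structure of the samples. With the additive effects of tissue and genotype removed first, 1 of 100 groupings, the real one, gave 2896 or more for MYB50 (highest other 1444). For MYB61, 9 of 100 groupings, the real one included, gave 18 or more (highest other 247).

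The MYB50 knockout differed from Col-0 at 7109 probe sets in xylem and 6715 in cork, and the MYB61 knockout at 299 and 1274. A Ler background of the MYB50 plants was argued against by 16 probe sets at least 4-fold lower in the Ler family, where the median position of the MYB50 arrays between Col-0 (0) and Ler (1) was 0.04; other backgrounds were not tested. Calls were spread over the chromosomes, with a highest share of 1.06 times that of the genes tested. This argues against calls gathered on 1 chromosome. It cannot decide on a short linked segment, or on a linked change that acts on genes elsewhere. With the actin 3' to 5' ratio as a covariate 6829 xylem calls remained in number. This argues against RNA quality, as read from actin, as the whole cause in xylem. The 3' to 5' ratio of the GAPDH control was not used as a covariate. It was 1.43 ± 0.056 in MYB50 knockout cork against 1.197 ± 0.051 in Col-0 cork, and 1.196 ± 0.103 against 1.1 ± 0.132 in xylem (SD, n = 3). For MYB61 in cork 654 of 1274 calls remained in number with the actin ratio. What stays open is an effect of the knockout, a linked chromosome segment, and RNA quality that the actin ratio does not read. A separate growth, age or nutrient state of the MYB50 plants stays open too. That state may have differed and cannot be told apart from genotype, because the labels give no growth batch and each group is 1 genotype.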

How the results depend on the processing

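The fits in Col-0 alone, with the added lists and without 2 cork arrays (1 of low weight, 1 labelled a repeat) were chosen after the data were seen. Counts of probe sets stayed within 1.5 times the reported value in all alternatives run for xylem versus cork, MYB50 in xylem and cork, max4, axr1, the MYB50 difference of effects, MYB61 versus MYB50, abi1 versus aba1 and max4 versus axr1. Fitting only the arrays compared gave 39 for MYB61 in xylem (299 reported), 230 for MYB61 in cork (1274), 1018 for abi1 (1661) and 3 for the MYB61 difference of effects (18), with fewer residual degrees of freedom by construction. Array weights gave 3219 for abi1, 6892 for aba1 (4317) and 200 for the MYB61 difference; the background covariate gave 500 for MYB61 in cork and 8 for the MYB61 difference; the actin 3' to 5' ratio as a covariate gave 654 for MYB61 in cork; the stricter filter gave 10 for the MYB61 difference, and leaving out the 2 cork arrays 148; the cause was not tested. Without single arrays the counts ran from 174 to 373 for MYB61 in xylem, from 774 to 1275 for MYB61 in cork, from 940 to 1672 for abi1 and from 6 to 150 for the MYB61 difference, 150 without MYB61 knockout cork replicate 1, whose array weight was 0.22. The replicate numbers showed little pairing of the arrays: 11 of 63 pairs with the same number correlated above 0.1 (median 0.01). This does not show whether xylem and cork of the same number came from the same plants. With the replicate block the counts were 8808 for xylem versus cork, 278 for MYB61 in xylem and 1180 for MYB61 in cork. Of 84 list and comparison pairs, camera called 10, camera with an estimated correlation 4 and fry 42; the added lists gave 61 of 406, 19 of them with an estimated correlation. For named genes, 26665 of 28096 alternative values kept direction and side of the threshold, counting 110 sign changes called in neither fit; 1296 became weaker, 131 stronger and 4 reversed, uncalled each time: PRL (0.10), GH9B13 (0.05) and nad4L (-0.16) for xylem versus cork in Col-0 alone, and EXLA3 (-0.29) for the MYB50 difference with a pseudocount of 1; the cause was not tested. The balance of rises and falls was not stable where it was near even: the larger side turned in some alternatives for xylem versus cork, MYB61 and MYB50 in cork, abi1, the MYB50 difference of effects (1350 higher, 1334 lower with only the arrays compared), MYB61 versus MYB50 (4222 higher, 4408 lower without a filter), abi1 versus aba1 (1205 higher, 1206 lower without a filter) and max4 versus axr1. Quantile normalization moved the median of all probe sets by at most 0.035. Signal near background limits dim genes, since 29.6% to 37.1% of the probe sets of an array were under 16.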

Other observations

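The tests of a response particular to max4 and axr1 and of the scanner background in abi1, and the resampling of groups, were chosen after the result was seen. Some of the largest falls of the MYB50 knockout were also falls in aba1, and these comparisons share no control arrays. NRT2.5 was 9.50-fold lower in MYB50 knockout xylem, 12.5-fold lower in its cork and 5.44-fold lower in aba1. AT4G31330 and AT5G59050 were 5.96-fold and 7.26-fold lower in MYB50 knockout xylem and 5.93-fold and 4.18-fold lower in aba1, and AT1G80130 was 33.6-fold lower in MYB50 knockout cork and 5.25-fold lower in aba1. Over all probe sets 940 were lower in both MYB50 knockout cork and aba1, where independent calls would give 511. There were 558 higher in both (399 if independent), and 689 went opposite ways (911 if independent). With r = 0.16 the likeness over all probe sets was weak. Among changes of at least 2-fold, 33 were lower in both (2.9 if independent) and 42 higher in both (15.9 if independent). The excess was seen in both directions and was relatively larger for falls. MYB50 knockout xylem was not set against aba1 in this way. NRT2.5 also differed between the wild types, at 38.4 ± 3.00 in Col-0 hypocotyls and 451 ± 38.9 in Ler hypocotyls (SD, n = 3), a difference that was not tested. In max4 it was at 430 ± 23.0 and in axr1 at 118 ± 4.34.

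A set of 373 probe sets at least 2-fold higher in both max4 and axr1, with STZ and CML38 among the 179 with a gene name, was followed in the other mutants. Of the set 59.2% were called higher in abi1, 70.8% in aba1 and 68.6% in MYB50 knockout xylem, against 4.7%, 11.8% and 20.4% of all probe sets. In the MYB61 knockout 30.8% were called higher in xylem and 39.1% in cork, against 1.2% and 3.9% of all. These shares argue against a response particular to max4 and axr1. They are not independent of each other: abi1 and aba1 shared the Ler arrays, and the knockouts shared the Col-0 arrays of each tissue. The set itself was chosen against Col-0 hypocotyl arrays that max4 and axr1 shared, so low values on those arrays alone could place a probe set in it. In MYB50 knockout cork the set did not rise: 20.1% were higher against 21.3% of all, 85 were lower and 75 higher, with a median log2 of 0.03. The scanner background was lower in abi1 than in Ler (98.9 ± 15.2 against 122 ± 8.37, SD, n = 3), and with it as a covariate 96.4% of the members called higher in abi1 were still called, which argues against background as the cause there. In max4 100% were still called, which decides nothing, since its background hardly differed from that of Col-0 (81.3 ± 5.24 against 76.6 ± 12.7). The actin 3' to 5' ratio was 1.659 ± 0.18 in abi1 and 1.261 ± 0.023 in Ler (SD, n = 3). Whether RNA quality contributed to the rise of the set in abi1 was not tested. Handling of the plants before freezing that differed between samples may contribute: over 27 arrays of 9 other groups the set varied 2.18 times as much between replicates as genes of like intensity (1.59 to 2.61 when the groups were resampled, since the members move together), from 1.11 times within aba1 to 3.42 times within MYB50 knockout xylem, while 105 probe sets lower in both mutants also varied more, by 1.62 times. Effects of the genotypes stay open beside it, as untested.

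In MYB61 knockout cork 15 of 43 plastid photosynthesis genes, 7 of 20 plastid expression genes and 5 of 13 mitochondrial genes were lower, and in axr1 11 of 13 mitochondrial genes, all camera calls lost with an estimated correlation (adjusted p = 0.254, 0.184, 0.118 and 0.218). For the plastid transcripts in MYB61 knockout cork, carry-over of RNA without a poly(A) tail into the labelling and a different amount of plastids could each contribute, and cannot be told apart from the data. The 25S control was lower than in Col-0 cork (2820) both there (1493) and in MYB50 knockout cork (766), where 25 of 43 plastid photosynthesis genes fell, but in MYB50 knockout xylem, where it was 387 against 1245, 12 of 43 rose. The mean of 1493 was carried in large part by MYB61 knockout cork replicate 1, at 186.5. Replicates 2 and 3 were at 1903.6 and 2389.3. The mitochondrial fall in axr1 is left unexplained: plastids do not carry those genes, and the 25S control was 2506 ± 441 in axr1 against 2380 ± 362 in Col-0 (SD, n = 3), not lower. Over 36 arrays, as deviations from group means, organelle-encoded signal correlated with the 25S control at r = 0.36 (rho 0.44, permutation p = 0.087, adjusted p = 0.17 over 4 relations; r = 0.26 without the 2 farthest arrays). The 63 plastid members alone gave r = 0.38 (rho 0.47, permutation p = 0.073, adjusted p = 0.17) and the 13 mitochondrial members r = 0.1 (rho 0.01, permutation p = 0.57, adjusted p = 0.57). Plastid-encoded and nuclear photosynthesis transcripts correlated at r = 0.29 (rho 0.19, permutation p = 0.27, adjusted p = 0.36; r = 0.39 without the 2 farthest arrays). A genotype effect on organelles was not tested apart from these.

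Other splits of the samples were counted for each comparison. For xylem versus cork (8831 real, 3680 the highest other of 100 splits) and MYB61 versus MYB50 (8153 real, 4640 the highest other), 1 split, the real one, reached the real value. That share of 0.01 is the smallest that 100 splits can give. It makes chance unlikely without excluding it. The 10 splits of 3 arrays against 3 are too few for a share under 0.05. Their real values and highest others were 299 and 69 for MYB61 in xylem, 1274 and 53 for MYB61 in cork, 7109 and 48 for MYB50 in xylem, and 6715 and 4 for MYB50 in cork. For hypocotyls they were 1661 and 10 for abi1, 4317 and 1 for aba1, 7105 and 0 for max4, 5833 and 2 for axr1, 2456 and 1 for abi1 versus aba1, and 5135 and 0 for max4 versus axr1.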
